A study of Mus musculus with 2 samples.

How the data were processed

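Genomic DNA of E14 cells, a mouse embryonic stem cell line, was cut with MspI, an enzyme that cuts at CCGG whether or not the inner CpG is methylated, then converted with bisulfite and sequenced, per the labels' protocols. This is reduced representation bisulfite sequencing (RRBS), which reads mainly the first bases next to MspI sites. The series has 1 RRBS library and 1 genotyping library of sonicated DNA; the genotyping library was not analysed here. The authors deposited 2 tables of methylation calls for the RRBS library, with a fraction of methylated reads for each strand-specific CpG cytosine, once with reads placed on the mm9 genome and once on an E14 version of it on the same coordinates. The submitters' processing notes name CASAVA 1.8, Bowtie 0.12.7, SAMtools, BSMAP 2.74 and mm9 without giving their roles. The read filters are not given in the sources used here.

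The deposited fractions run from 80 to 100% in both tables, with no coverage. A cytosine that is not listed was either not read, not placed or called below 80%, and these cases cannot be separated. The depth behind each value is unknown, so no interval or floor that needs it is given. Coverage minimums, coverage weighting, Fisher tests on reads and classes of low and middle methylation were planned and could not be run. The planned difference of 30 points could not be run either, since levels in these tables can differ by at most 20 points. Both tables come from the same reads, so no p-value between references is given. With 1 library, intervals and permutation tests over 1 Mb blocks of the genome, or over genes, describe the spread within this library only.

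Each deposited line carries 5 bases of context. On placed chromosomes the context equalled the NCBIM37 genome (mm9) in 100% of positions of the mm9 table and in 97.1% of the E14 table. Differing bases were taken as E14 substitutions, which are seen only inside listed contexts. Genes and their starts come from gencode vM1 on the same build. Coordinates are 1-based.

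Measures, thresholds, gene lists and the rule for named genes were set before the data were examined. They were the listed positions per table, the level per table, chromosome and local number of listed positions, differences per position and per 1 kb window with 5 or more positions in each table, strand agreement, and the mean level of listed positions within 1 kb of gene starts for 9 gene lists. Genes of these lists with 5 or more positions could be named, with the 3 highest, the 3 lowest and the 3 with the largest difference between references per list. Windows named are the 10 with the largest level difference among those with 10 or more positions in each table, and the 5 with most positions on 1 reference only, for each reference. Intervals are 95% percentile intervals from 1000 bootstrap draws of 1 Mb blocks or, for gene lists, of genes. Permutation tests over blocks used 100000 draws, and each gene list was set against 10000 random lists of the same size, matched on the number of listed positions per gene, all two-sided, with Benjamini-Hochberg adjustment over the lists. The adjustment over both tests of positions on 1 reference only was added after their p-values had been seen.

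A further measure was chosen after seeing that only levels of 80% or more are listed, namely the share of reachable CpG cytosines that are listed. It leads the account of CpG density, gene starts and gene lists, with random lists matched on reachable cytosines per gene. The rule for named genes was then applied to it with 5 or more reachable cytosines. Genes without a listed reachable cytosine tie for lowest, and those named were picked from that tie after their values were seen. A cytosine is called reachable if it lies within 50 bases of an MspI end in the read direction, on a fragment of 80 to 300 bp. Both limits were set from the listed positions themselves. The share was first computed over all MspI ends. After the values for the X chromosome had been seen, it was restricted to ends whose bisulfite-converted 50 bases occur once among the 3240876 MspI ends, and that restriction turns the direction of the comparison of X with autosomes. Such ends are 78.7% of all, 81.1% on autosomes and 54.9% on X. Density matching, the list of CpG-dense gene starts and the limit of 2% for blocks with few E14-only positions were also chosen after seeing the data.

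Tested on simulated data over 13017 gene starts, the list test called 100% of lists of 20 genes at a share of 25% or 40%, 5% of lists at a share of 10%, and 5% of lists drawn at random. Each share was tried on 20 lists only. All genes of a simulated list had the same share, unlike the real lists, whose genes varied widely. Shares of other genes were shuffled, which removed their link to the number of reachable cytosines. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, matplotlib 3.10.9 and samtools 1.23.1. Alternatives tried were other window sizes and position minimums, thresholds, density widths, distances from gene starts, fragment lengths, choices of ends and weights, and the other reference.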

Results

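RRBS of E14 mouse embryonic stem cells gave 1 library, whose methylation calls exist on the mm9 genome and on an E14 version of it. The calls on mm9 hold 1329372 CpG cytosines and those on E14 hold 1419056, all with a level of 80% or more. There are no replicates, and the depth behind each value is unknown.

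The first question was what a genome matched to the cell line changes in the calls. The E14 reference listed 6.75% more cytosines than mm9. Both tables shared 1309621 positions, 109435 were on E14 only (7.71% of the E14 table) and 19751 on mm9 only (1.49% of the mm9 table). Chromosome 14 gained most, with 12.5% of its E14 positions on E14 only, followed by chromosomes 7 (10.8%) and 8 (9.60%). Chromosome 10 had 4.16% and the X chromosome 2.32%, close to its share on mm9 only (2.22%).

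Of the E14-only positions, 29.9% lay at CpGs that mm9 does not have (32755 positions at 31795 CpGs), and 78.1% of these stood at TG or CA in mm9. A further 4.96% were mm9 CpGs with a changed neighbouring base and 21929 positions had the mm9 context but a substitution seen within 50 bp. No substitution was seen within 50 bp of the remaining 45.0% of placed E14-only positions, a share that is too high by an unknown amount because substitutions are visible only inside listed contexts. Of those within a read of an MspI site, 10.5% lay on MspI ends that occur more than once, against 1.12% of shared positions. The E14 contexts held 39466 substituted positions, 69.2% of them T-to-C or its complement; since only methylated E14 CpGs are listed, CpGs lost in E14 are seen only where a listed context overlaps them (14 mm9-only positions), and this share does not describe the genome. Substitutions also created 8868 MspI sites that were seen inside listed contexts.

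**Figure D1:**
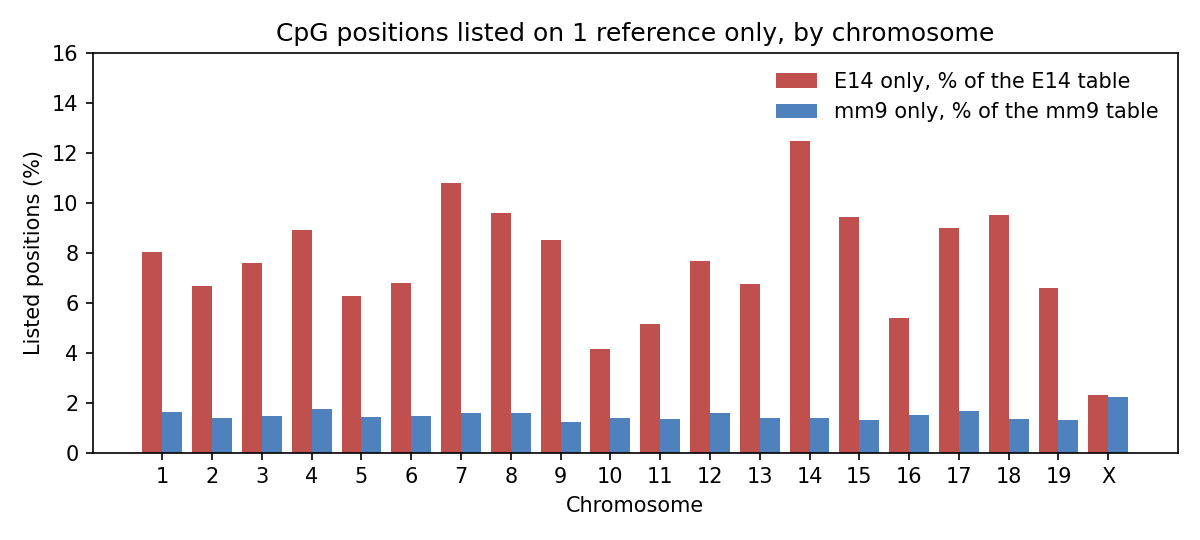
Bars give, for each chromosome except Y, the percentage of the E14 table listed on E14 only (red) and of the mm9 table listed on mm9 only (blue), from 1 library. Chromosome 14 reaches 12.5% on E14 only, while on X both bars are near 2%, at 2.32 and 2.22%.

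The gain was uneven along chromosomes. Over 2464 blocks of 1 Mb, the E14-only share had a median of 5.90%, and its 95th percentile was 30.2%. The highest block, chromosome 8 from 31000001 to 32000000, had 54% (81 of 150 positions). By contrast 679 blocks had under 2%. The longest runs of such blocks were chromosome 16 from 16000001 to 28000000, with 28 E14-only positions of 7072, and chromosome 10 from 70000001 to 81000000, with 43 of 12569. Across blocks, which are not independent replicates, the share of created CpGs rose with the E14-only share among unchanged contexts (Pearson's r 0.922, Spearman's rho 0.902, permutation p = 1e-05 for each, the smallest the draws can give). With the mm9-only share r was 0.176 and rho 0.131 (permutation p = 1e-05 for each). These were the 2 relations computed over blocks, so the Benjamini-Hochberg adjusted values equal the raw ones. Neither was planned. Blocks with a low share came in runs, and shuffling blocks singly ignores this likeness of neighbours. The p-values may therefore be too small by an unknown amount.

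The windows richest in E14-only positions included Dux on chromosome 10, a multicopy homeobox gene, with 26 such positions from 57687001 to 57688000 and no created CpG among its E14 positions. Others were 41643001 to 41644000 on chromosome 3 outside genes (19 positions), the window of Gm11400 and Sfi1 on chromosome 11 from 3050001 to 3051000 (15), 129770001 to 129771000 on chromosome 5 outside genes (14), and that of Opn4, the gene of the photopigment melanopsin, on chromosome 14 from 35404001 to 35405000 (13). On mm9 only, the window of Gm10807 on chromosome 10 from 57694001 to 57695000 held 13 positions, 73147001 to 73148000 on chromosome 3 held 12, and 113534001 to 113535000 on chromosome 13, the windows of Brd3 (27356001 to 27357000) and Gm10801 (98502001 to 98503000) on chromosome 2, held 11 each.

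Most shared positions had the same level on both references, among positions at 80% or more on each. Of the shared positions, 1706 (0.130%) had another level on E14, with a tolerance of 0.05 points. By 20 points, the planned threshold and the largest difference these tables can hold, 14 were higher and 28 lower on E14. By 10 points, 130 were higher and 330 lower. The mean level was 98.97% on each reference (98.95 to 98.98%) over all listed positions, and 95.3% on each over reachable ones. Of 59854 windows of 1 kb, 0 differed by 10 points, which says little because positions under 80% are not listed. The window of Bai2 on chromosome 4 (129688001 to 129689000) had the largest difference, 98% over 10 positions on mm9 and 89.3% over 11 on E14. The window of Coro2a on chromosome 4 (46594001 to 46595000) had 92.2% on mm9 and 100% on E14, and that of Spen on chromosome 4 (141032001 to 141033000) had 96.4 and 89.7%. The windows of Ccdc88c, Dapk2 and Scube1 had differences of 3.41 to 3.81 points, and those of Lrrc32, Dennd3, Crtac1 and Ptprf of -3.75 to -3.28 points.

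Positions on E14 only had a mean level close to that of shared positions in the same 1 kb window, 98.6% for each over 52281 positions. Over 2062 blocks the mean difference was 0.0749 points (SD 2.81, sign-flip permutation p = 0.226, adjusted p = 0.226). For positions on mm9 only it was 0.150 points over 1889 blocks (SD 3.23, sign-flip permutation p = 0.0428, adjusted p = 0.0855 over both tests). Against shared positions within 100 bp, those on mm9 only were higher by 0.285 points (adjusted permutation p = 0.0172), while the difference for E14 only was -0.0604 points (adjusted permutation p = 0.437). All these sets hold only levels of 80% or more. Exactly 100% was reached by 90.9% of E14-only, 89.5% of mm9-only and 90.4% of shared positions. This limit bounds how far the means can differ. Of placed E14 positions, 54.0% lay beyond a read of any MspI site, and 99.7% of these stood at exactly 100%. Within a read 79.4% did, so the means also reflect the positions beyond a read. Positions on 1 reference only and shared ones were not compared within a read alone. Whether positions on E14 only or mm9 only tend to be lower cannot be judged, since levels below the limit are not listed. The 2 strands of a CpG were both listed at 48362 CpGs on E14. Their median absolute difference was 0 points, the mean 2.8 points, and across CpGs, which are not independent replicates, Pearson's r was 0.0809 and Spearman's rho 0.0902. A CpG entered only with both strands at 80% or more, and at 71.5% of these CpGs the strands were equal. This limit bounds both the differences and the correlations, so they cannot measure how far strands agree over all levels.

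CpG-dense sequence had few listed cytosines. Of 1087927 reachable cytosines, 23.9% were listed on E14 (95% interval 23.6 to 24.4%). With 1 to 4 CpGs within 100 bp on either side the share was 41.3% and with 5 to 9 it was 38.8%. It was 14.8% with 10 to 14, 1.65% with 15 to 19, and 0.127% with 20 or more. Within 1 kb of a gene start 1.85% were listed, against 36.9% in coding exons, 22.7% in other exons, 35.5% in introns and 36.8% between genes. In sequence with 5 to 9 CpGs the share was still 8.78% near gene starts (8.18 to 9.40%) and 53.3% in coding exons (52.3 to 54.3%). Over all ends and fragment lengths, the share within 50 bases was 12.3% with 1 to 4 CpGs and 16.5% with 5 to 9, so these classes changed order. It was 5.64% with 10 to 14, 1.17% with 15 to 19 and 0.111% with 20 or more. Among listed positions alone, those with 10 to 19 listed positions within 100 bp on either side had a mean level of 97.8% (97.6 to 98.0%), against 99.1% for those with 1 to 4. This difference of -1.29 points was -0.375 within 50 bp and -2.17 within 250 bp. Within 50 bp the class of 10 to 19 (98.6%) was above that of 5 to 9 (98.2%). These classes include positions beyond a read of any MspI site, 99.7% of them at exactly 100%, and may differ in how many they hold. Over reachable listed positions the mean level was 95.6% with 1 to 4 CpGs and 95.1% with 5 to 9. It was 94.3% with 10 to 14, 94.1% with 15 to 19 and 95.5% with 20 or more.

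**Figure D2:**
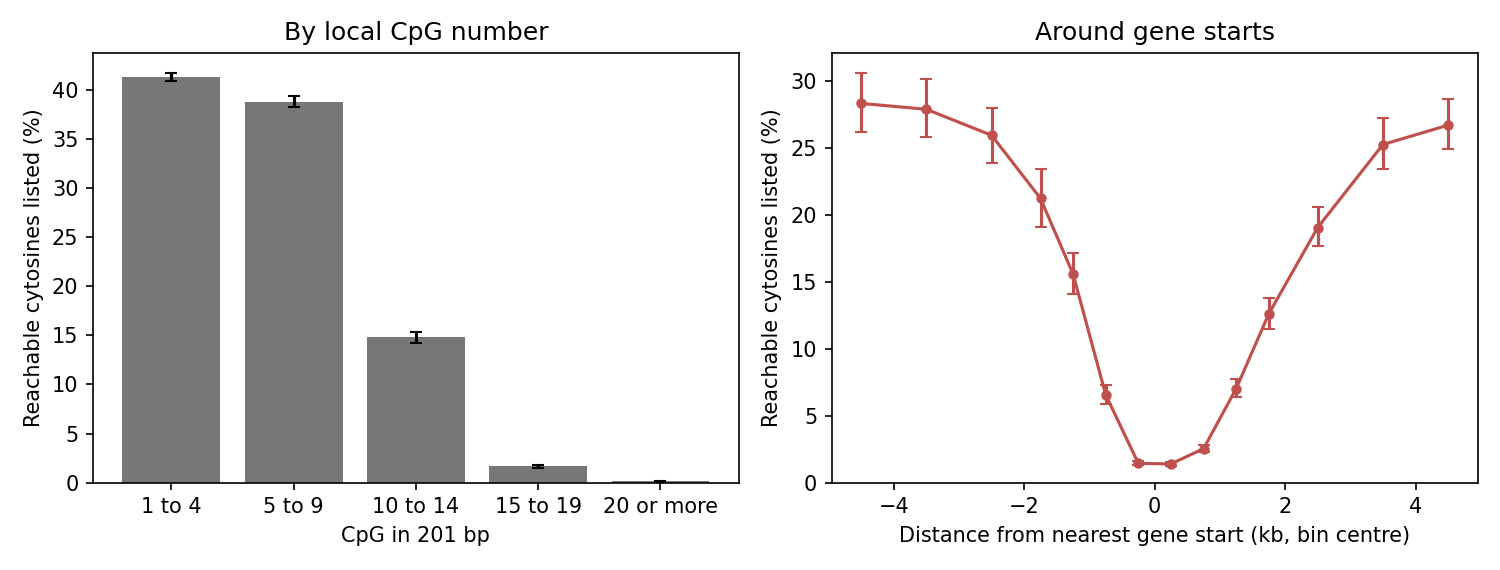
Percentage of reachable CpG cytosines listed at 80% or more on E14, by number of CpGs within 100 bp on either side (left) and by distance in kb from the nearest gene start, negative upstream (right); error bars are 95% block bootstrap intervals within 1 library. The share drops from 41.3 to 0.127% with CpG number and has its minimum, 1.39%, in the first 500 bp after the start.

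Cytosines of the same MspI end tended to be listed together. After a listed first cytosine, 84.0% of later cytosines of the same end were listed (83.8 to 84.3%), against 3.89% after a first cytosine that was not listed (3.79 to 4.0%). These pooled values mix sequence of different CpG density. With 1 to 4 CpGs the shares were 84.2 and 11.3%, and with 20 or more they were 58.5% (46.0 to 71.2%) and 0.0664%. At 47478 MspI sites with both neighbouring fragments in range, the minus strand was listed in 56.3% of cases where the plus strand was and in 16.1% where it was not. Being read is part of being listed, so these shares do not measure methylation alone.

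Germline genes, active in germ cells and mostly silent in other cells, had a higher share of listed cytosines near their starts than matched random lists. On average 40.2% were listed over 19 genes (24.8 to 57.1%), against 7.83% in the random lists (permutation test, p = 0.0002, the smallest the draws can give, adjusted p = 0.0018). This measure was chosen after seeing the data, and the planned test on levels did not call the list. With fragments of any length the mean was 20.9% (adjusted permutation p = 0.0018). Of these genes 12 had 20% or more, 4 had less and 3 had none. Mov10l1 (chromosome 15, 88813339 to 88885582) and Tdrd9 (chromosome 12, 113209770 to 113307065), of the piRNA pathway that silences transposons, had 6 of 6 each. Tex101 (chromosome 7, 25453031 to 25457069), a germ cell surface protein gene, had 20 of 23. Ddx4, Rpl10l and Tdrd1 had none listed of 10, 19 and 5. By the share listed, the references differed most at Hormad1, Asz1 and Sycp1. Hormad1, needed for meiotic chromosome pairing, had 8 listed on E14 and 5 on mm9, of 14. Asz1 had 11 and 8, of 17, and Sycp1, of the synaptonemal complex, had 4 and 6, of 15.

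Imprinted genes, expressed from 1 parental copy, had a mean share of 19.8% over 27 genes (8.92 to 32.8%), against 6.17% for random lists (permutation test, p = 0.0004, adjusted p = 0.0018), on the same measure chosen after seeing the data. The mean rests on a few members, since the median was 0 and 15 genes had none. Only levels of 80% or more are listed, so methylation of 1 parental copy alone could go unlisted. The share listed therefore does not measure imprinting, and a gene with none was not shown to be unmethylated. Peg10 (4697306 to 4710514) and Sgce (4624350 to 4697204) on chromosome 6, which share a start region and the same cytosines, had 12 of 12. Fkbp6 (chromosome 5, 135767574 to 135825895) had 12 of 14. Plagl1 (chromosome 10, 12810497 to 12851500) had 14 of 20 on E14 and 16 on mm9, the only imprinted gene tested whose count differed between references. Igf2r was among the 15 genes with none, of 52. Without Sgce the mean was 16.7% (adjusted permutation p = 0.0279), and with fragments of any length 12.3% (adjusted permutation p = 0.0018).

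The planned test of these lists, on the mean level of listed positions, called none of the 7 lists with such genes. Germline genes averaged 96.9% over 16 genes, against 97.6% for random lists, a difference of -0.710 points (permutation test, p = 0.194, adjusted p = 0.664). Imprinted genes averaged 97.6% over 14 genes, against 97.9%, a difference of -0.335 points (permutation test, p = 0.556, adjusted p = 0.664). Pluripotency genes had 98.1% (3 genes), liver genes 96.8% (2 genes), trophoblast and neuronal genes 100% (2 genes each) and developmental regulators 100% (Nkx2-5 alone), with adjusted permutation p of 0.664 to 1. No housekeeping gene or gene of the DNA methylation machinery had 5 listed positions. On this measure Mov10l1, Piwil1 and Tdrd9 were at 100% and Tex101, Asz1 and Slc25a31 lowest among germline genes, at 93.8, 93.0 and 92.2%. The references differed most at Sycp1 (1.09 points higher on E14), Hormad1 (-1.07) and Dazl (-0.874), which encodes a germ cell RNA-binding protein. Among imprinted genes, Cdh15, H19, Igf2, Nespas, Nnat and Rtl1 were at 100%, and Magel2, Sgce and Mcts2 were lowest, at 93.5, 93.7 and 94.9%. The measure can vary only between 80 and 100%. It takes all listed positions near a start, reachable or not. Nkx2-5 had 8 of them, though none of its 15 reachable cytosines was listed.

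The other lists did not pass the test on shares. Developmental regulators had a mean share of 0.268%, against 2.5% for random lists (35 genes, adjusted permutation p = 0.299). Hoxc10 had 3 of 32, and the remaining 34 genes, with Cdx2, Pax6 and T among them, had no listed reachable cytosine. Housekeeping genes had 0.866% (21 genes, adjusted permutation p = 0.278), with Ldha at 1 of 6, Actb at 1 of 66 and 19 genes at 0. Genes of the DNA methylation machinery had 0.366% (13 genes, adjusted permutation p = 0.914); Mbd1 had 2 of 42, and Dnmt1, Dnmt3a and Dnmt3b had none. Pluripotency genes had 6.39% (19 genes, adjusted permutation p = 0.995), from Dppa3 (6 of 6) and Esrrb (3 of 14), while Pou5f1, Sox2 and Klf4 had none. Trophoblast genes had 1.99% (8 genes) and neuronal genes 6.97% (9 genes), with an adjusted permutation p of 0.931 for each. The trophoblast mean was below its random lists (2.93%) but above them on fragments of 60 to 500 bp (3.33 against 1.46%) and of any length (11.4 against 6.06%, 11 genes, adjusted permutation p = 0.284), and the pluripotency mean, below its random lists (6.91%), was above them within 500 bp (7.88 against 6.39%). Of the liver list only Fgb was tested, with 5 of 5 (adjusted permutation p = 0.278). With fragments of any length 7 liver genes averaged 27.6% (adjusted permutation p = 0.284), neuronal genes 2.99% and pluripotency genes 3.12%, and none of these lists passed.

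**Figure D3:**
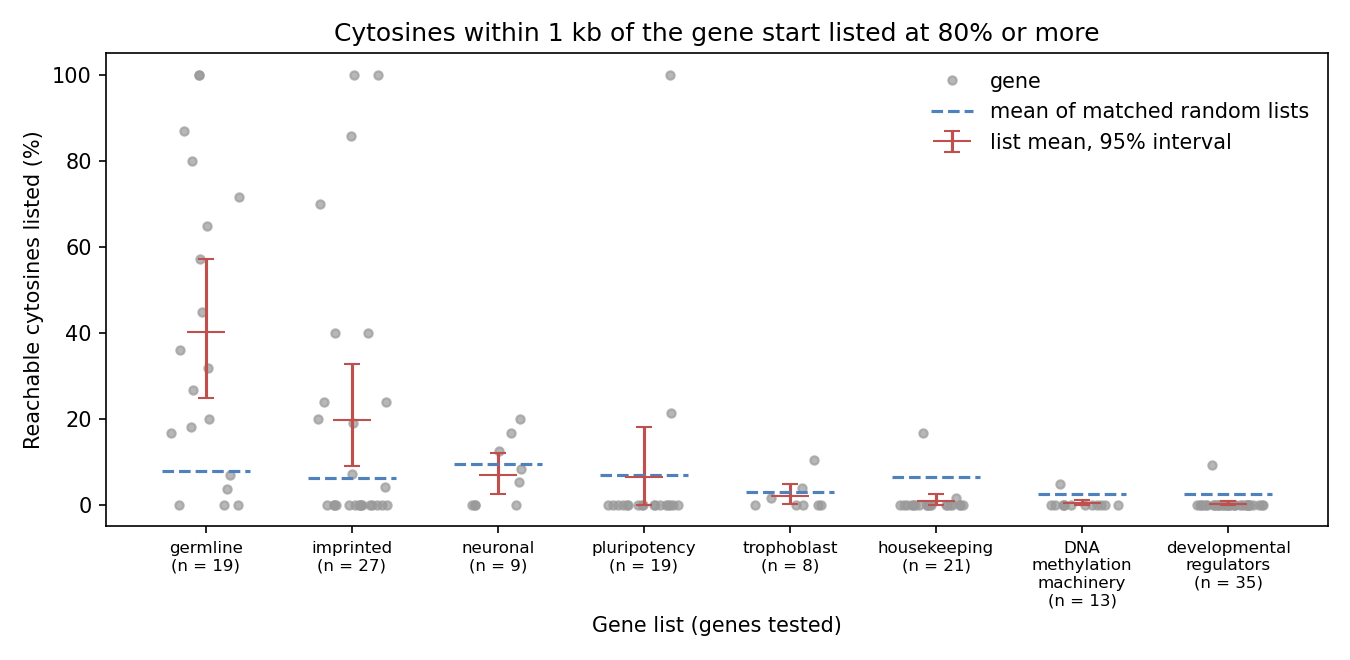
Percentage of reachable cytosines within 1 kb of the gene start listed at 80% or more on E14; each dot is a gene, red bars are list means with 95% bootstrap intervals over genes, and dashed lines are means of matched random lists. Germline genes average 40.2% and imprinted genes 19.8%; the liver list, with 1 gene, is left out.

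Across all 13017 gene starts tested, 86.5% had no listed reachable cytosine and 806 had 20% or more of their reachable cytosines listed. The references differed at 167 of them, with more on E14 at 121 and more on mm9 at 46.

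No direction can be given for the mean level of listed positions on X, since it depended on which positions were taken. Over all listed positions, as planned, the block means were 98.7% on X (SD 0.731, 160 blocks) and 99.1% on autosomes (SD 0.356, 2404 blocks), a difference of -0.367 points (permutation test over blocks, p = 1e-05, the smallest the draws can give). The difference was -0.188 points with each position weighing the same and -0.197 within a read of an MspI site, and with both it was 0.0138 points (permutation p = 0.820). Over reachable positions, a choice made after seeing the data, X was higher by 0.540 points (permutation p = 1e-05), and pooled over these positions X had 96.0% and autosomes 95.3%. In sequence with 1 to 9 CpGs X was higher by 0.513 points (permutation p = 1e-05), and with 10 or more CpGs the difference was 1.02 points (permutation p = 0.223), or 1.09 with each position weighing the same (permutation p = 0.0002). Over positions, X averaged 98.8% on E14 (98.7 to 98.9%), and so did chromosome 11 (98.7 to 98.9%).

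No direction can be given for the share of cytosines listed on X. On ends that occur once, the block mean was 33.3% on X (SD 16.8) and 28% on autosomes (SD 12.5), a difference of 5.25 points (permutation test over blocks, p = 2e-05). Over all MspI ends it was 12.5% on X (SD 5.05) and 18.3% on autosomes (SD 8.10), a difference of -5.77 points (permutation test over blocks, p = 1e-05). With fragments of any length it was -2.32 points (permutation p = 1e-05). Pooled over cytosines on ends that occur once, X had 24.1% and autosomes 23.9%. The restriction to such ends was made after the values over all ends had been seen.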

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

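The tests of reads longer than 50 bases, of unconverted DNA and of created MspI sites were chosen after the result was seen.

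On E14, 765159 positions (54.0% of placed ones) lay beyond a read of any MspI site of mm9 or seen as created in E14. RRBS should read little there, and 99.7% of these positions stood at exactly 100%, against 79.4% within a read. Longer reads are argued against, since the share listed showed little drop after the first 50 bases past a read. With 1 to 4 CpGs it was 2.14% in those bases, 2.06% in the next 50 and 2.18% in the later stretch used for comparison. With 5 to 9 CpGs these shares were 3.13, 3.13 and 3.17%. Pooled over 1 to 9 CpGs, the ratio to the later stretch was 1.07 (1.05 to 1.09). This ratio mixes both classes, whose proportions differ with distance, so it does not show an excess within a class. Over all CpGs the share was lower in the first 50 bases (2.07 against 2.39%), which mixes classes as well. MspI sites created in E14 and seen inside listed contexts reach 1.81% of the positions beyond mm9 sites. Created sites outside listed contexts are not seen, so this share is too low by an unknown amount and cannot decide the question. Unconverted DNA stays open: it predicted a share in CpG-dense sequence of at least 50% of that in sparse sequence, the bound against it was a ratio under 0.1, and the ratio was 0.234 (0.217 to 0.254), with 0.490% listed in dense and 2.09% in sparse sequence. This pooled ratio mixes distances. At 50 to 99 bases, 0.590% (15 to 19 CpGs) and 0.112% (20 or more) were listed, against 2.14% (1 to 4) and 3.13% (5 to 9). At 1000 bases or more the shares were 1.62 and 0.964%, against 1.58 and 3.19%. No biological explanation was tested, and whether these positions come from few reads cannot be judged without coverage.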

How the results depend on the processing

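Alternatives of all ends, fragment lengths, density matching, Sgce, position weighting, MspI reach, reachable positions and the mm9 strands were chosen after the data were seen. Of 102 alternative values 80 counted as the same, 1 became stronger, 5 moved and 16 reversed, and the cause of each change was not tested. For tests, the same meant an equal direction and side of the threshold. For counts it meant a close count, and for means and differences a value inside the interval of the main one. Many of the 80 were lists that passed in neither setting. The counts of windows could hardly have changed, since only levels of 80% or more are listed. Stronger: mm9-only positions against shared ones within 100 bp (0.285 points, adjusted permutation p = 0.0172). Moved: with classes at 90%, 95.2% of positions were in the top class on each reference instead of 100%; at 10 points, 460 shared positions differed instead of 42; the level difference by listed density was -0.375 points within 50 bp and -2.17 within 250 bp, instead of -1.29. Reversed: E14-only positions against shared ones within 100 bp (-0.0604, p = 0.437, sign-flip permutation); mean level on X within a read of an MspI site with positions weighing the same (0.0138 points) and over reachable positions (0.540 points, and 0.706 with positions weighing the same; 0.513 and 0.701 with 1 to 9 CpGs; 1.02 and 1.09 with 10 or more), all instead of -0.367; share on X over all MspI ends (-5.77 points) and any fragment length (-2.32), both instead of 5.25; with 1 to 9 CpGs (-9.67 and -4.37 instead of 1.31); with 10 or more CpGs over all ends (-0.170 instead of 3.30). Pluripotency genes within 500 bp (7.88%) and trophoblast genes on fragments of 60 to 500 bp (3.33%) or any length (11.4%) crossed their random lists without passing a test. Germline and imprinted genes passed under every alternative run on shares, with germline means of 20.9 to 41.8% and imprinted ones of 12.3 to 20.1%. Coverage minimums, coverage weighting, a list of sites by reads, the 30-point threshold and lower class limits could not be run, and the level test gave no value for developmental and trophoblast genes within 500 bp. No paired analysis was possible because the groups hold 1 library each. Unknown depth leaves open whether an unlisted cytosine was unread, not placed or called below 80%.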

Other observations

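The list of CpG-dense gene starts, the genes named from it and the tests of depth on X and of CpGs removed by E14 substitutions were chosen after values were seen.

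CpG-dense gene starts were rarely listed. There were 10439 starts with 10 or more reachable cytosines and a mean of 10 or more CpGs within 100 bp on either side. Of these, 9630 had no reachable cytosine listed and 54 had 30% or more listed. Beside Peg10, Sgce and Fkbp6, the highest included Otud6a on X (13 of 13), Fscn2, which encodes an actin-bundling protein of the retina (22 of 23), and Trim10 (11 of 12). The block of chromosome 4 from 145000001 to 146000000 had both 49.3% of its E14 positions on E14 only and 37.8% of its mm9 positions on mm9 only.

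Over all MspI ends in sequence with 1 to 9 CpGs, 18.6% of reachable cytosines were listed on X and 32.3% on autosomes, a gap of -13.7 points. On ends that occur once the gap was -1.93 points (-4.13 to 0.378), so reads that fit several places may account for most of it. Lower depth of a chromosome with 1 copy is argued against as the cause of most of the gap, since it would act on ends that occur once as well, where the share on X was 0.952 times that on autosomes (0.897 to 1.01), against 0.577 times over all ends. Whether any deficit is left on such ends is open. Block means there were 42.0% on X and 40.6% on autosomes (permutation p = 0.121), while with fragments of any length the difference was -4.37 points (permutation p = 1e-05). A smaller part from lower depth is open too. Over all ends, listed cytosines on X were more often at exactly 100% (62.2 against 55.4%). This was not computed on ends that occur once. Over all CpG numbers, listed cytosines on repeated ends had a higher mean level than those on ends that occur once (97.3 against 95.3%). No biological explanation was tested.

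Within a read of an MspI site, positions on mm9 only lay on repeated MspI ends 7.23 times as often as shared ones (8.07 against 1.12%, interval of the ratio 6.40 to 8.18), which is consistent with reads that fit several places. This was not particular to mm9, since 10.5% of such E14-only positions without a substitution seen also lay on repeated ends. Whether E14 substitutions removed CpGs of mm9-only positions could not be decided. Both tables come from the same reads and list only levels of 80% or more. A CpG lost in E14 would seldom reach that level on mm9, so few such cases could appear. With the other strand on mm9, it was also on E14 in 67.7% of 1245 cases (exact binomial interval 65.0 to 70.3%, treating positions as independent). The CpG was thus still listed on E14 in those cases, a small part of the 19751 mm9-only positions. An overlapping E14 context showed the CpG changed at 14 mm9-only positions. No biological explanation was tested, and most mm9-only positions within a read lie on ends that occur once, so repeated ends leave most of them unaccounted for.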
